A study of Brassica napus with 8 samples.

How the data were processed

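RNA sequencing of polyadenylated transcripts was carried out on 4 tissues of rapeseed (Brassica napus, an allotetraploid oil crop with an A and a C subgenome), cultivar Zhongshuang 11. The tissues were young leaf, seed labelled 50 DPA, dry seed and seed after 48 h of germination, with 2 libraries each. Per the labels' protocols, libraries were made with an Illumina TruSeq RNA kit and sequenced as paired reads on a NovaSeq. The labels do not say whether the 2 libraries of a tissue came from separate plants or harvests, so the p-values measure only the spread between these libraries, which may be technical.

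The deposited count tables hold whole-number counts per gene. One covers 3 tissues and the other all 4, and both list 106059 gene IDs. In the 6 libraries that the tables share, 0 values differed. The 4-tissue table has 1 line inside it that names alignment files in place of a gene, and this line was removed. Per the submitters' processing notes, FastQC, HISAT2, SAMtools and edgeR were used. Their versions, the read counter, the genome build and the annotation are not given in the sources used here. Among values above 0, between 80.5% and 85.4% per library were even. Such a pattern arises when both mates of a read pair are counted, so a sequenced fragment seems to give about 2 counts, and counting error is then larger than the counts alone imply.

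The deposited TMM tables hold a normalized signal, and no label records the step that made it. Tested on the files, each value equals the count times 1 constant per library to within 0.0033. The constants are those of CPM (counts relative to a fixed library total) with a TMM factor, and the factors differed by at most 0.000307% from those given by edgeR on all genes with a count. TMM (trimmed mean of M values) sets library scales on the assumption that most genes do not change. In the comparisons below, 59.6% to 77.4% of the genes tested were called changed. That assumption is therefore in doubt, and directions of change are relative to this scale.

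The main analysis started from the counts of all 8 libraries. Genes were kept by edgeR's filterByExpr (59062 genes), scaled by TMM, and tested by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with 1 mean per tissue and no covariate. All 4 tissues shared 1 estimate of the spread per gene. Libraries differed more in dry seed than in leaf, so p-values may be too small for dry seed and too large for leaf. Among genes with at least 100 CPM, germinating seed libraries differed nearly as much as dry seed ones, so the same holds there. All 6 pairwise comparisons were tested 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A gene was called highest in a tissue when it was higher there in all 3 comparisons of that tissue. Levels are TMM-normalized CPM, as mean ± SD of 2 libraries, whereas detected genes were counted on CPM without TMM factors, with the TMM scale as an alternative. Where both libraries of a tissue had 0 counts, a fold is a lower bound against a floor of 3 read pairs (6 counts) per library, which covers counting error only. Standard errors of log2 fold changes are the fold change over the square root of the F statistic.

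The design, the alternatives and 20 lists of genes by product name were fixed before the data were examined. None of the gene IDs matched the gene table used here, which describes another rapeseed assembly (Da-Ae), and the files do not pair IDs with names or coordinates. The lists, among them markers of seed coat, endosperm and root, could therefore not be applied (0 of 20), and genes are reported by ID. The rule for named genes, fixed with them, ranked the largest fold changes per main comparison and direction among genes past the threshold. Where IDs have no names, it printed the first 2 of each direction. Such genes also needed a mean of at least 50 CPM in the higher tissue and no overlap between the libraries of the compared tissues. Near-identical homoeologous and tandem copies are common in this genome, and the handling of reads shared by copies is not given, so the level of any single ID is uncertain to that extent.

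Library totals ran from 27635445 to 55721357 counts. A CPM of 1 then stands for 27.6 to 55.7 counts, well above the floor of 6 counts. The test was checked on simulated counts for the comparison of dry with 50 DPA seed, with 56192 genes in the fit. Library sizes and spread were those of the data, but each gene had 1 mean over all tissues, and 100 genes were changed per fold. The test recovered 42 of 93 genes changed 2-fold and 66 of 99 changed 4-fold, with median absolute log2 estimates of 1.02 and 2.01, and called 5 unchanged genes. In the data 59.6% of genes were called in this comparison, so these rates do not carry over to it. A count of adjacent gene pairs, used in the closing observations, gave a ratio of 1.00 to chance in shuffled data.

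Alternatives were DESeq2 size factors, upper-quartile factors, total counts alone, factors without the 100 most abundant genes, 2 other filters, DESeq2 1.42.0, limma 3.58.1 on the deposited TMM signal (pseudocounts of 1 and 0.1), stricter thresholds, fits on 2 tissues, the 3-tissue table, a replicate block and each library left out. Halved counts, a fit without young leaf and the split of the dry seed libraries were added after the data were seen, as were the TMM-scaled counts of genes found in 1 tissue and the comparisons of change patterns across tissues. No batch or date is given in the labels. The 3-tissue table lacks germinating seed, so its libraries may have been made apart from the others. Any comparison with germinating seed, and the genes called highest in it, could then hold a batch difference that cannot be told apart here.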

Results

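The study set out to compare expression between organs of rapeseed, as the counterpart of a chromatin profiling method for crop organs. Transcripts were measured in 8 libraries: young leaf, 50 DPA seed, dry seed and 48 h germinating seed, with 2 libraries each. Total counts were 35000319 and 36463920 in the young leaf libraries and 33861108 and 36535168 in those of 50 DPA seed. They were 35418139 and 27635445 in the dry seed libraries and 55721357 and 40730533 in those of germinating seed. Log2 levels correlated across genes between the 2 libraries of a tissue with Pearson's r from 0.965 in dry seed to 0.990 in young leaf.

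Seed libraries before germination used fewer genes and concentrated their transcripts in fewer of them than leaf or germinating seed. On CPM without TMM factors, genes with at least 1 CPM numbered 44480.5 ± 141 in young leaf, 35849 ± 175 in 50 DPA seed, 33258 ± 55.2 in dry seed and 43073.5 ± 21.9 in germinating seed (SD, n = 2). With TMM factors they numbered 43031 ± 77.8, 38696.5 ± 23.3, 34209.5 ± 96.9 and 40645 ± 55.2 in the same order, so the gap between germinating and 50 DPA seed was much smaller on that scale. In 50 DPA seed, the 10 most abundant genes took 21.02% ± 0.151 of all counts and the 100 most abundant took 45.4% ± 0.217. The 100 most abundant took 24.1% ± 0.930 in dry seed, 13.4% ± 0.0736 in young leaf and 8.58% ± 0.143 in germinating seed. These differences between tissues were larger than the spread between libraries, although 2 against 2 libraries allow no exact permutation p below 0.333. In both libraries of a tissue, 25133 genes reached 1 CPM in all 4 tissues. Young leaf and germinating seed shared 6126 genes that reached it in neither of the other tissues. Genes that reached it in a single tissue numbered 4553 in young leaf, 2705 in germinating seed, 1407 in 50 DPA seed and 950 in dry seed. With TMM factors these were 4376, 2186, 1905 and 1127, and young leaf and germinating seed shared 4154 genes found in neither of the other tissues.

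**Figure D1:**
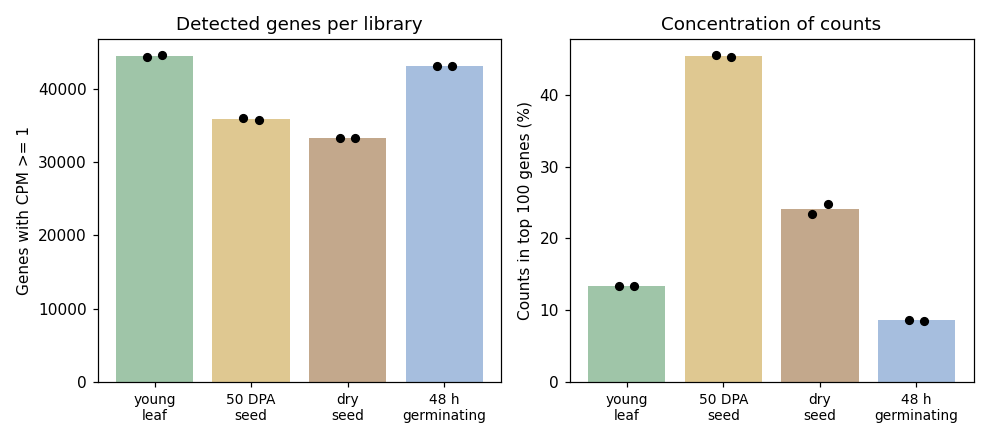
Left, number of genes with at least 1 CPM, without TMM factors. Right, share of counts in the 100 most abundant genes (%). Bars are means and points the 2 libraries of each tissue; 50 DPA seed shows the largest concentration, at 45.4%.

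Each tissue had a large set of genes that were highest in it against all 3 others. Young leaf had 11717 such genes, germinating seed 8792, dry seed 8627 and 50 DPA seed 6373, of 59062 tested. The 6373 genes highest in 50 DPA seed took 62.2% ± 0.250 of its counts, 11.5% ± 0.0137 of those of dry seed and 5.65% ± 0.00681 of those of germinating seed (SD, n = 2). Genes highest in dry seed took 59.2% ± 0.413 of its counts, 14.2% ± 0.113 in 50 DPA seed and 17.9% ± 0.0765 in germinating seed. Genes highest in young leaf took 51.7% ± 0.0695 of leaf counts and 8.40% ± 0.0685 of germinating seed counts, against 3.63% ± 0.0102 in 50 DPA seed and 3.09% ± 0.0369 in dry seed. The sets were defined on these libraries, so the shares in their own tissue describe them and are not independent evidence. With total counts alone as the scale, the sets held 3836 genes in 50 DPA seed, 7035 in dry seed and 12890 in germinating seed. With DESeq2 size factors they held 6542, 8716 and 8050 in the same order. Dry and germinating seed thus have no fixed order, whereas 50 DPA seed had the fewest genes on each scale tried. With a 2-fold minimum, dry seed had 5361 and germinating seed 5852.

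**Figure D2:**
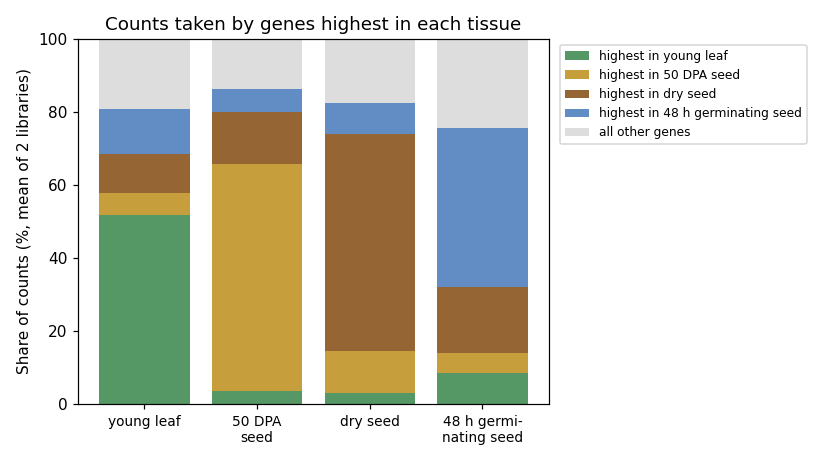
Share of counts (%, mean of 2 libraries) taken in each tissue by genes highest in young leaf, 50 DPA seed, dry seed or germinating seed, with all other genes in grey. Genes highest in a tissue take from 43.7% of counts in germinating seed to 62.2% in 50 DPA seed.

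The first comparison asked how 50 DPA seed differs from a vegetative organ. In 50 DPA seed, 18218 genes were higher and 22795 lower than in young leaf, 69.4% of the genes tested (edgeR quasi-likelihood test, adjusted p under 0.05). Levels differed at least 16-fold in 2956 of the higher and 3991 of the lower genes. The gene ZS11C01G025460 stood at 40920 ± 1170 CPM in 50 DPA seed and had 0 counts in both leaf libraries, at least 298000-fold lower (SD, n = 2; edgeR adjusted p = 1.57e-13). ZS11A10G002330 stood at 39860 ± 970 CPM and was also without counts in leaf, at least 290000-fold lower (edgeR adjusted p = 2.5e-13). In the other direction, ZS11A04G014400 stood at 2914 ± 7.29 CPM in leaf and had 0 counts in both 50 DPA seed libraries, at least 11800-fold lower. ZS11C06G019610 stood at 1231 ± 5.70 CPM in leaf, at least 4980-fold above 50 DPA seed (edgeR adjusted p = 1.48e-11). The median SE of a log2 fold change over all genes tested was 0.30. No count in leaf was seen for 1886 of the higher genes, and no count in 50 DPA seed for 4866 of the lower genes. The floor of 6 counts stood at 0.137 CPM in leaf and 0.247 CPM in 50 DPA seed, so the 2 numbers are not directly comparable. The 100 most abundant genes of leaf, 97 of which were lower in 50 DPA seed, took 13.4% ± 0.0700 of leaf counts and 0.413% ± 0.00778 of 50 DPA seed counts. These genes were picked for being abundant in leaf, so their direction is not independent evidence. Of the changed genes, 44.4% were higher in 50 DPA seed with TMM factors and 23.8% with total counts alone. That scale moved the median log2 change of all genes from -0.20 to -1.02, so directions are relative to the TMM scale.

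**Figure D3:**
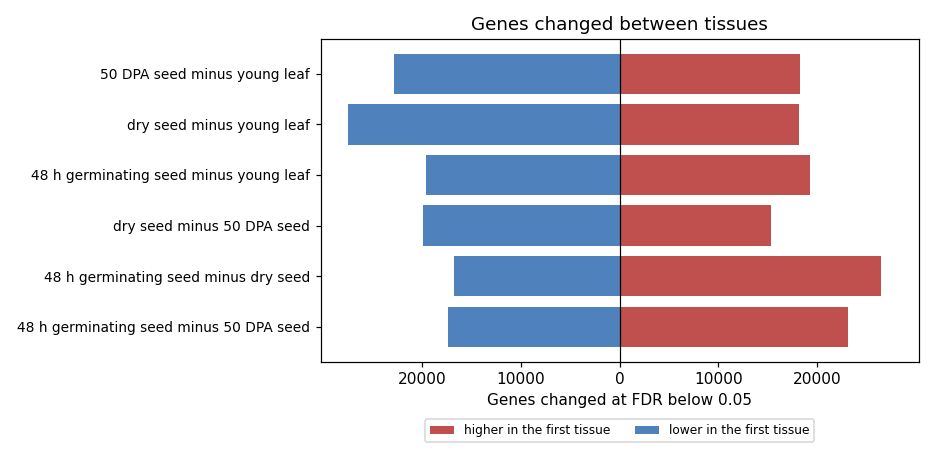
Number of genes higher (red, right) or lower (blue, left) in the first-named tissue of each comparison at an edgeR adjusted p below 0.05. Germinating seed against dry seed has 26415 higher genes, and dry seed against young leaf has 27504 lower genes.

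The next comparison set dry seed against 50 DPA seed. The labels do not say that the seed stages came from the same plants or seed lot. Rises and falls between stages therefore describe differences between separate samples. From 50 DPA to dry seed, 15304 genes rose and 19906 fell, 59.6% of those tested (edgeR quasi-likelihood test, adjusted p under 0.05). Log2 levels correlated across genes at 0.761, against 0.447 to 0.629 for the other pairs of tissues. Of the 100 most abundant genes of 50 DPA seed, 83 fell and 9 rose, and their share of counts went from 45.4% ± 0.222 to 9.48% ± 0.235 (SD, n = 2). Because these genes were picked for being abundant at 50 DPA, their direction is not independent evidence. ZS11C04G004770 rose from 0 counts to 95.3 ± 7.04 CPM, at least 386-fold (edgeR adjusted p = 3.41e-09), and it had no count in leaf or germinating seed either. ZS11C08G031740 rose from 0 counts to 80.9 ± 8.04 CPM, at least 328-fold. ZS11C02G005600 fell from 429.4 ± 0.705 CPM to 0 counts, at least 1940-fold lower, and stood at 36.3 ± 1.03 CPM after germination. ZS11A04G002400 fell from 326.4 ± 3.22 CPM to 0 counts, at least 1480-fold lower (edgeR adjusted p = 6.84e-10). The median SE of a log2 fold change was 0.31. The split between directions rested on the scale: 43.5% of the changed genes rose with TMM factors and 53.6% with total counts alone.

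Germination was addressed by the comparison of seed after 48 h with dry seed. By 48 h, 26415 genes had risen and 16802 had fallen, 73.2% of those tested (edgeR quasi-likelihood test, adjusted p under 0.05). Among the risen genes, 7765 had no count in either dry seed library, whereas 545 of the fallen genes had none after germination. The floor of 6 counts stood at 0.221 CPM in dry seed and 0.0944 CPM in germinating seed. A level without counts was thus easier to reach in dry seed, and the 2 numbers are not directly comparable. Of the 100 most abundant genes of dry seed, 98 fell and 1 rose, and their share of counts went from 24.1% ± 0.927 to 1.81% ± 0.0581 (SD, n = 2). These genes too were picked on the same libraries. ZS11C01G018040 rose from 0 counts to 616 ± 55.8 CPM, at least 2790-fold (edgeR adjusted p = 2.69e-11). ZS11A06G008930 rose from 0 counts to 493.8 ± 51.4 CPM, at least 2230-fold, and stood at 62.1 ± 0.0436 CPM in leaf and 10.2 ± 0.277 CPM in 50 DPA seed. ZS11C03G044890 fell from 300.2 ± 4.28 CPM to 0 counts, at least 3180-fold lower, after 156.5 ± 5.95 CPM at 50 DPA. ZS11C04G004770, the gene first detected in dry seed, fell from 95.3 ± 7.04 CPM to 0 counts, at least 1010-fold lower (edgeR adjusted p = 6.07e-10). The median SE of a log2 fold change was 0.32. The share of changed genes that rose was 61.1% with TMM factors and 73.1% with total counts alone, which moved the median log2 change of all genes from 0.59 to 1.21.

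**Figure D4:**
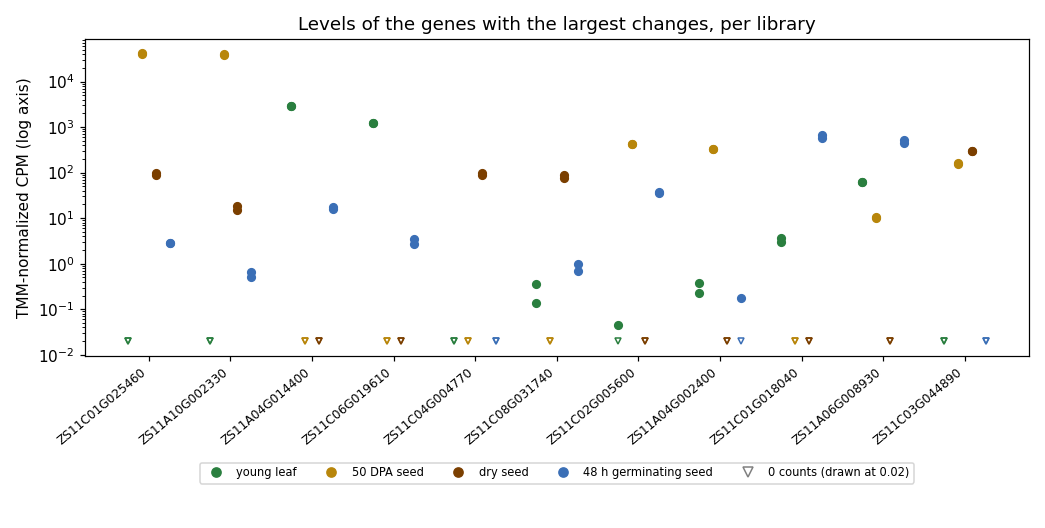
TMM-normalized CPM (log axis) of the 11 genes named by the rule, 1 point per library, coloured by tissue. Open triangles mark libraries with 0 counts, drawn at 0.02 CPM; ZS11C04G004770 has counts in dry seed alone.

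Changes from 50 DPA to dry seed and from dry to germinating seed ran in opposite directions for most genes that changed in both. Of the genes that fell from 50 DPA to dry seed, 63.9% (12717 genes) rose by 48 h, and of those that rose, 64.9% (9935 genes) fell. A fall was followed by a fall in 2883 genes, and a rise by a rise in 2465. Independent lists would share 8903 and 4354 genes in the opposite directions and 5663 and 6845 in the same ones. Both changes are measured against the same dry seed libraries. In 5 simulated sets with no change among seed stages, at most 1 gene was called in opposite directions and 0 in the same ones. Sets without change give almost no calls by design, so they cannot gauge opposite calls among changed genes. The covariance of the changes across genes was -0.134 in these sets, against -6.27 observed, a difference of -6.13. That gap shows only that the stages differ beyond noise. The r across genes was -0.504 observed and -0.554 simulated, so r alone does not separate these cases. The comparison was repeated with dry seed library 1 for the change from 50 DPA and library 2 for the change to 48 h, and the other way round, so that no library entered both changes. The opposite directions then held 12221 and 9356 genes in the first split, against 8651 and 4092 for independent lists. In the other split they held 12326 and 8911 genes, against 8914 and 3900. The covariance was -5.81 and -5.71, and r was -0.420 and -0.410. The split removes shared noise only: the dry seed level still enters both changes with opposite sign, which alone gives a negative r and an excess of opposite directions over independent lists.

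Young leaf and 50 DPA seed share no library with the germination comparison, so both changes could be set side by side. Of the 22795 genes higher in leaf than in 50 DPA seed, 62.7% (14290) rose from dry to germinating seed and 12.6% fell, against 33.4% that rose among the other genes (odds ratio 3.35). Of the 18218 genes higher in 50 DPA seed, 52.9% (9635) fell and 23.9% rose. Across genes, which are not independent replicates, the log2 changes correlated with Pearson's r of 0.421 and Spearman's rho of 0.440. Separate libraries remove shared noise only. Both changes are taken against seed before germination, and levels in 50 DPA and dry seed correlated at 0.761. That likeness alone can give a positive r and an odds ratio above 1.

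**Figure D5:**
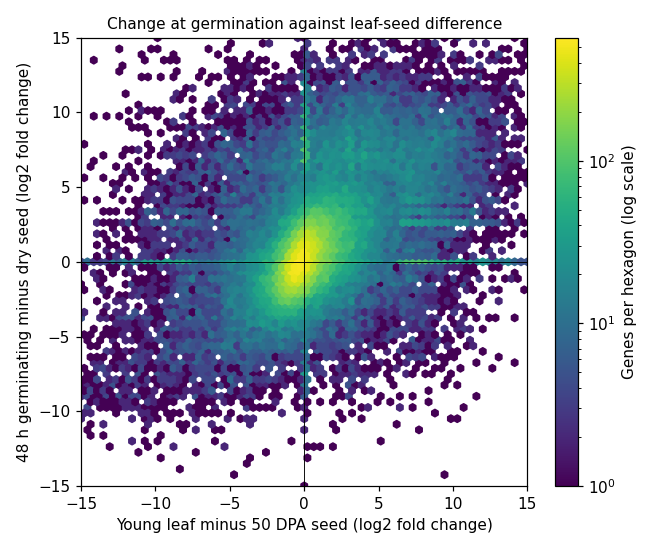
Log2 fold change of germinating over dry seed (vertical) against that of young leaf over 50 DPA seed (horizontal); colour gives genes per hexagon on a log scale. Genes extend along the rising diagonal (r = 0.421); 311 genes lie beyond 15 on an axis, and fitted values of genes with 0 counts depend on edgeR's prior count.

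The remaining comparisons were taken as counts of calls only (edgeR quasi-likelihood test, adjusted p under 0.05). Dry seed had 18185 genes higher and 27504 lower than young leaf, 77.4% of those tested. Germinating seed had 19228 genes higher and 19575 lower than young leaf, a balance that turned with the scale: 21143 against 18100 with total counts alone and 17897 against 20912 with DESeq2 size factors. It had 23126 genes higher and 17345 lower than 50 DPA seed, and there 57.1% of the changed genes were higher with TMM factors and 77.4% with total counts alone. Germinating seed correlated across genes at 0.628 with young leaf, 0.629 with dry seed and 0.602 with 50 DPA seed. Leaf correlated at 0.485 with 50 DPA seed and 0.447 with dry seed.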

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

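Halved counts, the split of the dry seed libraries, the changes compared across tissues and their alternatives were chosen after the data were seen. All 6 counts of changed genes stayed within 1.5 times their main value under every alternative run, from 27342 for dry against 50 DPA seed with a 2-fold minimum to 47526 for dry seed against leaf by limma on the deposited signal without a filter. With the replicate block, dry against 50 DPA seed gave 33394 genes against 35210; same-numbered libraries deviated from their tissue means with correlations of -0.0086 to 0.0064 over 6 pairs of tissues, so the numbers pair no libraries, and the block moved no count by over 1.5 times. Halving the counts called 33398 of those 35210 genes again in the same direction. Leaving out 1 library at a time gave 31775 to 36092 genes in this comparison, and for genes highest in young leaf 8530 to 13000 against 11717. With total counts alone, 3836 genes were highest in 50 DPA seed. Its TMM factors, 0.693 and 0.690, were the lowest of all libraries. Leaving the factors out therefore lowers its levels against the other tissues. What made these factors low was not tested. With a 2-fold minimum, 5361 were highest in dry seed, 5852 in germinating seed, and 6326 rose to dry seed then fell, since the minimum only removes calls. Detected genes at 0.5 CPM numbered 48799 in leaf, 40828.5 in 50 DPA seed, 37967 in dry seed and 47821.5 in germinating seed; on TMM-scaled libraries, 43031, 38696.5, 34209.5 and 40645 at 1 CPM, as the lower limit admits more genes and the factors move it per library. Of the genes higher in leaf than in 50 DPA seed, 55.6% to 67.7% rose at germination under the 22 alternatives that hold all 4 tissues. All 204 alternative values of the named genes kept direction and call, though not every alternative was run for them. These genes were picked for the largest changes and had 0 counts in the lower tissue, so this outcome was nearly certain beforehand. The lists by product name were not run, as no ID has a name. Lone libraries left by omission were assumed to vary like the other tissues.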

Other observations

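The tests of low counts and of overlap for adjacent IDs, the reading given to IDs 2 apart, and the fit without young leaf were chosen after the result was seen, as were the patterns themselves. Dry seed had 10933 genes lower than in each other tissue, against 7393 in young leaf, 4522 in germinating seed and 3444 in 50 DPA seed. These numbers were taken with TMM factors and were not counted on another scale. Dry seed had 15304 genes higher and 19906 lower than 50 DPA seed on that scale. On total counts alone it had 19077 higher and 16502 lower. The order of the tissues by genes lowest in them is thus relative to the TMM scale. The lists of the 100 most abundant genes overlapped by 39 genes between 50 DPA and dry seed and by 11 between dry and germinating seed. Leaf shared 2 with germinating seed, 1 with 50 DPA seed and 0 with dry seed, and 50 DPA and germinating seed shared 0. The 100 most abundant genes of germinating seed took 8.57% ± 0.144 of its counts, 3.56% ± 0.0527 in dry seed, 2.19% ± 0.00498 in leaf and 1.27% ± 0.0254 in 50 DPA seed (SD, n = 2).

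Genes whose IDs carry an A chromosome prefix were more often highest in germinating seed than those with a C prefix, at 16.1% of 27589 genes against 13.8% of 31359. By chromosome the share was 16.1% ± 1.03 (SD, 10 prefixes) against 13.8% ± 0.947 (SD, 9 prefixes). The exact 2-sided permutation p was 0.00013, and 0.00052 after adjustment over 4 tissues. Chance spread between chromosomes would rarely give such a difference in a pattern fixed beforehand. This pattern was chosen after the data were seen, which the adjustment does not cover, so chance is not excluded. The difference was 2.09 percentage points within 5 strata of mean expression (jackknife SE 0.488), against 2.27 without strata, which argues against a difference in mean expression, and it was 2.15 to 3.01 points under the other 4 scalings. The shares were 11.3% against 10.4% for 50 DPA seed (adjusted exact p = 0.00701), 14.9% against 14.3% for dry seed (0.201) and 19.6% against 20.02% for leaf (0.529). All these shares are of genes kept by the filter, which kept 27589 of 44373 A IDs and 31359 of 61069 C IDs. Taken over all IDs, the shares and their order in leaf would differ. No biological explanation was tested, and reads lost or shared between homoeologous copies, and the reading of the prefix as a chromosome, were not tested either.

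Genes with neighbouring IDs were more often highest in the same tissue than chance gives, taking ID order as gene order. Adjacent IDs gave 4710 such pairs against 3537 expected, a ratio of 1.332 (SD of 100 shuffles within prefixes 0.0163), and the ratio was 1.46 for dry seed and 1.23 for leaf. IDs 100 apart gave 0.994, which argues against chromosome-wide composition. IDs 2 apart gave 1.109 (SD 0.0143), above 1 by more than 2 SD, the criterion set beforehand against reads of an overlapping adjacent gene; that criterion left out a gene overlapping both of its neighbours, which would tie these IDs too, so without coordinates such reads cannot be told apart from shared regulation at either distance. Tandem copies with shared reads or shared regulation remain possible and were not tested.

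Genes higher in leaf than in 50 DPA seed tended to rise at germination. The likeness of 50 DPA and dry seed levels alone can give such a pattern. The correlation across genes was 0.538 among the 29531 genes with the higher mean expression and 0.337 among the others. It was thus not confined to genes with low counts. The compared changes share no library, so counting noise alone would not give a positive r, and this split was no test of it. A biological difference between the tissues stays open as untested, since the IDs have no names, and so does a difference in the preparation of the germinating seed libraries, for which no batch is given.

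Among genes with at least 100 CPM, the median SD of log2 levels was 0.0207 in leaf and 0.0773 in dry seed. It was 0.0417 in 50 DPA seed and 0.0760 in germinating seed. The main fit pooled these unlike spreads. Fitted on its 2 tissues alone, dry against 50 DPA seed gave 29568 changed genes of 46462 tested. The main fit gave 35210 of 59062. Fitted likewise, counts of changed genes also fell in the other comparisons with dry seed. They rose in those without it, as in germinating seed against leaf, at 44200 against 38803. The filter kept other genes in each fit, so these counts do not isolate the effect of pooling. Without both leaf libraries, dry against 50 DPA seed gave 32805 changed genes.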
